A study of Mus musculus with 6 samples.

How the data were processed

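Total RNA was extracted with a column kit from flash-frozen colon tissue and checked for integrity, and libraries were made by standard Illumina protocols, per the labels' protocols. The 6 libraries form 2 groups, control and knockout, with 3 replicates each, as the tissue label of each sample gives them. A single deposited table gives, per the file headers, a read count and an FPKM value (fragments per kilobase, scaled by library total) for each library and each of 34745 genes. The counts deposited by the authors are whole numbers and are not normalized. Among genes with ample counts in every library, the ratio of count to FPKM followed the column total, up to 1 factor per gene. This held within 0.001 log2 units for 100% of those genes. Gene lengths were not used in that check. The submitters' processing notes name HISAT2 2.0.4, StringTie 1.3.0 and edgeR without a role for each, and the builds GRCh38 and mm8. The coordinates in the table match neither note: of 34267 gene identifiers found in GENCODE M21, on the mouse build GRCm38, 27699 (80.8%) had exactly the same start and end and 99.94% overlapped their locus, so coordinates are given as the table has them, on GRCm38. Strandedness, trimming and the treatment of reads that fit several genes are not given in the sources used here. The series' design text speaks of duplicates, while each group has 3 samples.

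Because the table holds counts, the main test was the one fixed for that case before the data were examined: edgeR 4.0.16 in R 4.3.3, with TMM normalization, edgeR's own filter on low counts, and the quasi-likelihood test of knockout against control without a replicate block, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The design had otherwise assumed a table of FPKM values alone, to be tested with limma on log2(FPKM + 1). CPM values are counts scaled to library totals after TMM. Standard errors of log2 fold changes were derived from the test statistic. The exact permutation test of 3 against 3 cannot go below p = 0.1, so no test of single values was used. A gene with 0 reads throughout a group is given a fold of at least its value against 3 counts over that group, which covers counting error only; medians of lists did not change when such genes were set to that bound. After TMM scaling, 3 counts in a library are 0.174 to 0.219 CPM, and 15819 genes passed the filter.

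Gene lists (42, covering channels, immune and tissue cell types, position along the colon and pathways) were fixed at the same time, and 39 with at least 5 measured members were tested with camera (limma 3.58.1) at its preset correlation of 0.01, with an estimated correlation and with fry, which asks whether a list moves on balance one way. Symbols were matched to the table directly or through RefSeq synonyms. GO and KEGG terms were those the table attaches to genes, with 15 to 300 tested members. The rule for named genes was fixed with them: the 7 TRPC genes; the 10 highest and 10 lowest log2 fold changes among genes past the threshold, with groups not overlapping and a mean of at least 1 CPM in the higher group, leaving out predicted models and immunoglobulin or T cell receptor segments; up to 4 members with the smallest p of each list that was past the threshold or had a member past it; the 2 most abundant members of other cell-type lists; and 3 genes for each of at most 6 terms. That the 6 terms are the 3 with the smallest p among the higher and the 3 among the lower terms was decided after the terms were seen. Some genes that this rule names are not reported here.

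Alternatives were DESeq2 1.42.0, RLE factors, no filter on low counts, 2 filters on FPKM, quantile normalization, array quality weights, limma on log2(FPKM + 1) and log2(FPKM + 0.1), named genes only, a size threshold of 2-fold, a replicate block, and leaving out each library in turn. The table carries no comparison by the authors, so that alternative was not run. To compare a library with the others of its group, its counts were fitted as a weighted sum of theirs by weighted least squares over genes with a fitted count of at least 10, and squared deviations were divided by the variance that counting alone gives.

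The tests were checked on simulated data. For 3 against 3 libraries and about 15602 genes per set, edgeR recovered 81.7% of genes changed 4-fold and 99.3% of those changed 16-fold, with 4.6% of calls false; for 3 against 2 libraries it recovered 72% and 98.7%, with 3.8% false. In the 3 against 3 sets DESeq2 made 11.3% false calls. The simulated libraries were independent and had the same spread in both groups. The knockout libraries here spread more than the controls, and their replicate 3 lay close to a sum of the others, so these rates need not hold for the data. Camera called 10 of 10 simulated lists of independent genes that were shifted and 0 of 10 that were not. In the real lists the estimated correlation between members ran from -0.065 (squamous epithelium) to 0.922 (enteric neurons, glia and interstitial cells of Cajal). The simulation therefore does not show how often camera at its preset correlation calls unshifted lists of correlated genes. A simulated weighted sum of knockout replicates 1 and 2 gave deviations of 0.66 times counting noise and a simulated separate library 15.4 times. The first took the observed counts as exact, which sets it below 1. The second rests on an assumed spread between libraries. Neither stands for material pooled before sequencing.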

Results

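RNA sequencing counted the transcripts of colon tissue from age-matched male mice. Of the 6 libraries, 3 came from mice labelled TRPC-hepta knockout, which by the series title lack all 7 TRPC proteins, and 3 from TRPC-hepta control mice. TRPC proteins are calcium-permeable cation channels of the plasma membrane. Every mouse was treated for 6 days with DSS (dextran sulfate sodium), a polysaccharide that injures the colonic epithelium and is used to induce colitis. The control libraries held 16819662, 17584992 and 16864863 counted reads and the knockout libraries 13816295, 14529028 and 15505327, over 34745 annotated genes. No untreated mice were analysed here, so the effect of DSS itself was not measured. The labels do not state whether the replicates came from separate animals, so p-values measure only the spread between these samples.

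The knockout libraries were spread differently from the control libraries. Log2 CPM (counts scaled to library totals) correlated across genes at Pearson r = 0.97 to 0.976 between control libraries and at 0.877 between knockout replicates 1 and 2. Knockout replicate 3 correlated at 0.954 with each of those. These values are across genes, which are not independent replicates. The counts of knockout replicate 3 were close to 0.497 times those of replicate 1 plus 0.595 times those of replicate 2. Its squared deviations from that sum had a median of 2.63 times counting noise over 15526 genes. The control libraries, each fitted on the others of its group, gave 6.91, 7.16 and 9.43. Of 5167 genes that differed at least 2-fold between knockout replicates 1 and 2, 94.5% lay between them in replicate 3. Counts of genes are therefore also given without knockout replicate 3.

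**Figure D1:**
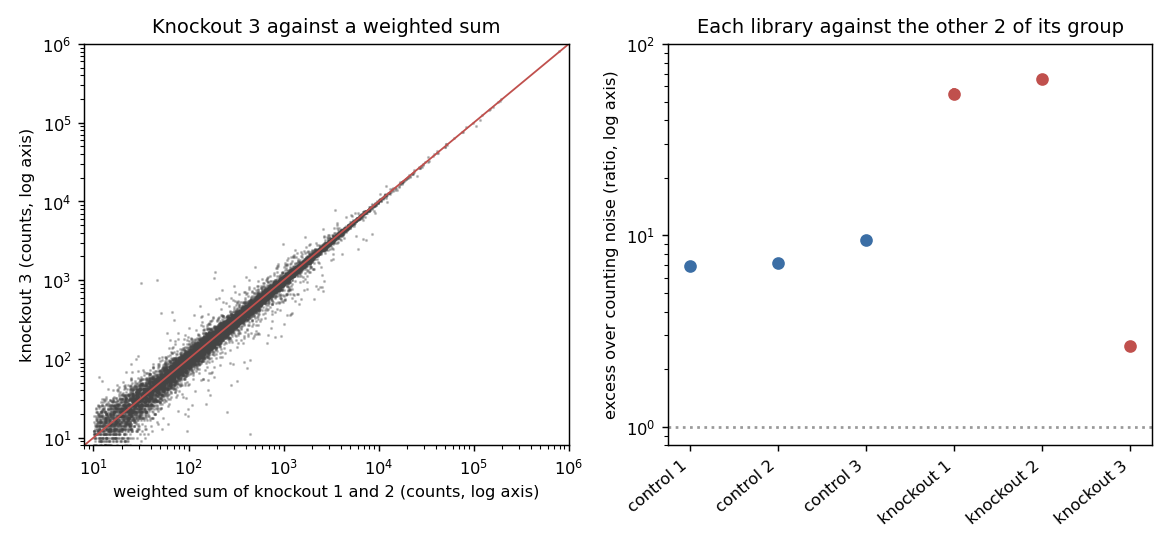
Left, counts of each gene in knockout replicate 3 (y axis, log scale) against the weighted sum of knockout replicates 1 and 2 (x axis, counts, log scale), 1 point per gene, with the line of equality. Right, the median squared deviation of each library from the weighted sum of the other libraries of its group, in multiples of counting noise (log axis, dotted line at 1, bars for 95% bootstrap intervals over genes): knockout replicate 3 sits at 2.63, below the other 5 libraries.

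The first comparison concerned the deleted genes, as a check on the labels. Trpc1 (GRCm38 chromosome 9, 95705082 to 95750375) had the most reads of the family, with 8.97 ± 1.80 CPM in the control and 8.01 ± 1.76 CPM in the knockout (SD, n = 3 each). Trpc4 (chromosome 3, 54156035 to 54318471) had 4.08 ± 1.52 against 2.84 ± 2.06 CPM. Trpc6 (chromosome 9, 8544196 to 8680565) had 1.42 ± 0.27 against 1.3 ± 1.14 CPM. In knockout replicates 1, 2 and 3, Trpc1 stood at 9.97, 6.57 and 7.48 CPM, Trpc4 at 5.12, 1.09 and 2.31 CPM and Trpc6 at 2.49, 0.219 and 1.19 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 0 of these 3 genes were past the threshold, at adjusted p = 0.735 to 0.958. Adjusted over the list alone, p was 0.964 for each. None had an unadjusted p under 0.05, and DESeq2 called 0. Trpc7 (chromosome 13, 56773113 to 56895789) had 16 reads over the control libraries and 18 over the knockout libraries, with 0 in knockout replicate 2, too few for the filter on low counts. Without that filter, Trpc7 had a log2 fold change of 0.26 (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.929). Trpc2 and Trpc5 had 0 reads in all 6 libraries, which at this depth allows at most 0.174 to 0.219 CPM in a library (3 counts, counting error only). An allele that removes part of a gene can leave reads from its other exons. The deleted parts are not given in the sources used here, so counts over whole genes neither check nor contradict the labels.

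The second comparison asked which transcripts differed between the genotypes under DSS. Transcripts of inflammation were higher in the knockout. S100a9 and S100a8, calcium-binding proteins abundant in neutrophils, rose from 0.177 ± 0.174 to 63.4 ± 52.2 CPM and from 0.261 ± 0.127 to 45.4 ± 34.4 CPM (SD, n = 3 each). Lcn2, an iron-sequestering antibacterial protein, rose from 1.45 ± 0.60 to 275.5 ± 224.7 CPM and stood at 501.3, 51.9 and 273.3 CPM in knockout replicates 1, 2 and 3. Il1a, a cytokine of the interleukin-1 family, rose from 0.103 ± 0.178 to 11.2 ± 1.1 CPM. Other genes were read in 1 group and almost absent from the other. Ifi202b, an interferon-inducible gene, had 0 reads in the control libraries and 52.2 ± 30.7 CPM in the knockout, at least 869-fold higher against 3 counts over the group. Trim12a fell from 88.2 ± 10.1 CPM to 0.066 ± 0.063 CPM, with 3 reads left over the knockout libraries (1320-fold, 95% counting interval 451 to 6400).

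Of 15819 genes tested, 278 were past the threshold (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 172 higher and 106 lower in the knockout. At an unadjusted p under 0.05 there were 2529. All 278 had groups that did not overlap, as did 21.6% of the genes tested, where chance gives 10%. The 278 included 30 predicted models or genes without a symbol and 3 immunoglobulin or T cell receptor segments. The count rested on single libraries. It was 15 (6 higher, 9 lower) without knockout replicate 3, 31, 20 and 29 without control replicate 1, 2 and 3, 320 without knockout replicate 1 and 1825 without knockout replicate 2. Knockout replicate 3 lay close to a weighted sum of replicates 1 and 2. If it shares material with them, counts that keep it, here and below, treat dependent libraries as independent. The counts without knockout replicate 1 or 2 may then be too high. The 15 genes were all among the 278, and all 278 kept their sign and an unadjusted p under 0.05 without knockout replicate 3. Since the 278 were chosen on data that include the remaining libraries, that outcome was nearly fixed in advance and is no separate support. DESeq2 called 1453 genes, among them all 278.

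The other genes of the 10 largest increases were Hist2h2bb, Hist1h2al, Psca, St6galnac1 and Gbp2b. Hist2h2bb and Hist1h2al carry histone symbols but are annotated here as a lincRNA and a processed pseudogene; they had 0 reads in the control libraries and were at least 102-fold and 32.1-fold higher against 3 counts over the group. Psca, a surface antigen, had 2 reads over the control and 516 over the knockout libraries (286-fold, 95% counting interval 78.9 to 2370). St6galnac1, a sialyltransferase, had 2 and 402 reads (223-fold, 61.3 to 1850). Gbp2b, a guanylate-binding protein gene, rose from 1.07 ± 0.45 to 160.1 ± 36.0 CPM. Among the 10 largest decreases, Trim5 fell from 26.2 ± 7.9 to 0.112 ± 0.042 CPM, and Rpl29, a ribosomal protein gene, from 106.9 ± 8.3 to 0.862 ± 0.330 CPM. Hsd3b2, a steroid dehydrogenase gene, fell from 67.4 ± 8.8 to 0.561 ± 0.373 CPM. Gp2, a glycoprotein that binds bacteria on M cells, had 0 reads in the knockout and was at least 17.7-fold lower against 3 counts over the group. Acot12, Adamts18, Cyp2e1, Nxpe5 and Pydc4 fell with log2 fold changes of -5.69 ± 0.77, -5.56 ± 0.75, -5.48 ± 0.89, -5.07 ± 0.76 and -5.06 ± 0.66 (SE). Of the 62 genes past the threshold that the rule for named genes picked, Gbp2b, Hsd3b2, Rpl29, Trim12a and Trim5 stayed past it whichever library was left out. There were 11, 6 and 8 past it without control replicate 1, 2 and 3, and 60, 62 and 5 without knockout replicate 1, 2 and 3. Histone-like, ribosomal protein, Trim, guanylate-binding protein and Ifi200-family genes have near-identical copies. How reads shared between copies were counted is not given in the sources used here, so their values are uncertain.

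**Figure D2:**
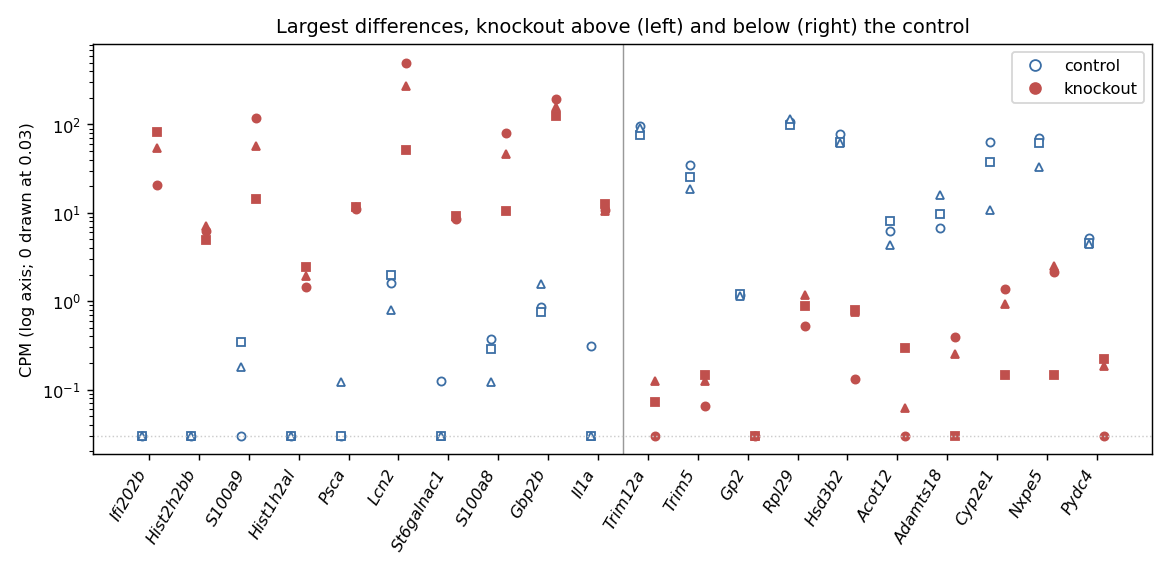
CPM (y axis, log scale, 0 drawn at 0.03) of the 10 genes with the largest increase and the 10 with the largest decrease in the knockout, 1 point per library, open for control and filled for knockout, with circles, squares and triangles for replicates 1, 2 and 3. The groups do not overlap for any of the 20 genes, and Lcn2 spans 51.9 to 501.3 CPM within the knockout.

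**Figure D3:**
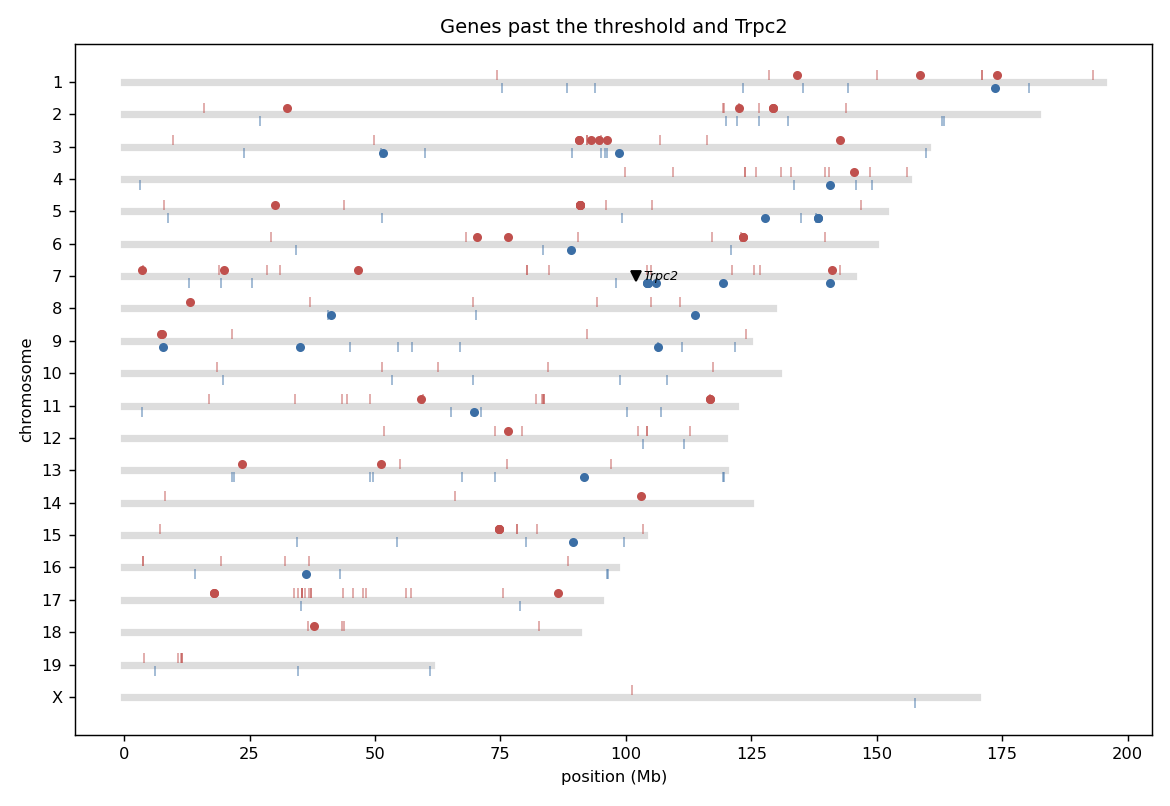
Positions (x axis, Mb, GRCm38) on each chromosome (y axis) of the 278 genes past the threshold, red above the line for genes higher and blue below it for genes lower in the knockout, as dots where the difference is at least 16-fold and as ticks otherwise. A black triangle marks Trpc2 on chromosome 7, and 9 of the 278 genes lie within 10 Mb of it.

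Neutrophil and chemokine genes were higher in the knockout. Of 22 measured neutrophil markers, 11 rose and 0 fell (20 and 1 adjusted over the list alone), with a median log2 fold change of 4.04. Besides S100a8, the examples are Clec4e, a receptor for microbial glycolipids (6.10 ± 0.73, SE), Clec4d (4.72 ± 0.62) and Hdc, the histamine-forming enzyme (3.93 ± 0.48). Of 27 chemokines, 9 rose and 0 fell (15 and 0 adjusted over the list alone). Cxcl2, which attracts neutrophils, rose from 0.644 ± 0.195 to 41.8 ± 28.7 CPM, and Ccl2, which attracts monocytes, from 2.38 ± 0.46 to 23.4 ± 10.8 CPM. Cxcl12 rose from 25.4 ± 1.6 to 90.9 ± 18.5 CPM and Cxcl13, which attracts B cells, from 16.8 ± 4.1 to 83.5 ± 20.1 CPM. Both lists were past the threshold in camera with its preset correlation, at Benjamini-Hochberg adjusted p = 1.85e-28 for neutrophil markers and 2.24e-14 for chemokines. Both calls were lost with a correlation estimated from the libraries (adjusted p = 0.209 and 0.126 with an estimated correlation), but held in fry (adjusted p = 0.0411 and 0.0283) and whichever library was left out. The neutrophil median lay 4.64, 2.73 and 3.92 log2 units above the control mean in knockout replicates 1, 2 and 3. The number of neutrophil markers past the threshold was 1, 0 and 0 without control replicate 1, 2 and 3, 0 without knockout replicate 3 and 20 without knockout replicate 2. For chemokines it was 0 without any 1 control replicate or knockout replicate 3, and 14 without knockout replicate 2. Chemokine genes have close relatives, and their values are uncertain to that extent.

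Cytokines and macrophage markers moved the same way. Of 17 inflammatory cytokines, 3 rose and 0 fell (12 and 0 adjusted over the list alone): Il1a, Il1b (1.60 ± 1.14 to 47.9 ± 3.1 CPM) and Il6 (0.621 ± 0.228 to 12.6 ± 4.1 CPM). Il11 stood at 1.63 ± 0.83 and 12.0 ± 5.1 CPM and was not past the threshold. Of 26 monocyte and macrophage markers, 2 rose and 0 fell (21 and 0 adjusted over the list alone): Cd14, the endotoxin co-receptor (25.5 ± 6.5 to 114.9 ± 21.2 CPM), and Lyz2, a lysozyme (68.5 ± 6.3 to 122.2 ± 5.6 CPM). Csf1r and Msr1 had log2 fold changes of 1.19 and 1.70 and were not past it. The list test (camera, Benjamini-Hochberg) gave adjusted p = 2.24e-14 for each list (adjusted p = 0.209 for each with an estimated correlation). The cytokines past the threshold numbered 2, 1 and 0 without control replicate 1, 2 and 3, 0 without knockout replicate 3 and 10 without knockout replicate 2. The macrophage markers numbered 0 without any 1 control replicate or knockout replicate 3, and 17 without knockout replicate 2.

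Genes of matrix breakdown and defence were higher as well. Of 26 matrix proteases and inhibitors, 3 rose and 0 fell (18 and 0 adjusted over the list alone). Mmp3, a metalloproteinase, rose from 5.34 ± 1 to 153.8 ± 85.5 CPM, Mmp8, the neutrophil collagenase, from 0.162 ± 0.127 to 9.5 ± 7.85 CPM, and Serpina3g from 7.22 ± 2.21 to 46.7 ± 24.7 CPM. Mmp10 had a log2 fold change of 3.87 and was not past the threshold. Of 25 epithelial antimicrobial genes, Lcn2 and Saa3, an acute-phase protein (22.3 ± 3.0 to 1028 ± 838 CPM), rose and 0 fell (12 and 1 adjusted over the list alone). Ltf and C3 had log2 fold changes of 3.94 and 4.2 and were not past it. Of 21 complement and coagulation genes, F10, coagulation factor X, rose (0.377 ± 0.198 to 7.26 ± 1 CPM) and 0 fell (14 and 1 adjusted over the list alone). C1ra, Cfp and F13a1 had log2 fold changes of 2.52, 1.22 and 2.74. As lists they had camera's Benjamini-Hochberg adjusted p = 4.13e-14, 2.01e-05 and 1.13e-10 for these 3 lists (adjusted p = 0.323, 0.209 and 0.323 with an estimated correlation). Of 12 genes of MHC class II antigen presentation, all had positive fold changes and 0 were past the threshold of edgeR (10 at an unadjusted p under 0.05, 5 by DESeq2, 9 adjusted over the list alone). H2-Aa stood at 243 ± 118.3 and 779.9 ± 264.8 CPM, and H2-DMb1, Cd86 and Cd80 had log2 fold changes of 1.36, 1.60 and 2.59. Its camera p was 5.31e-07 after Benjamini-Hochberg adjustment (adjusted p = 0.322 with an estimated correlation). By fry, the 4 lists had adjusted p = 0.13, 0.0411, 0.117 and 0.115 in the order given. Members of these 4 lists past the threshold numbered 0 without knockout replicate 3 or any 1 control replicate, and 22, 9, 13 and 1 without knockout replicate 2. Leaving out knockout replicate 1 gave 2, 4, 2 and 0, with Mmp8 no longer among them. Saa3 has close relatives, and its value is uncertain.

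Lymphocyte markers were shifted as lists, with no single gene past the threshold. Of 24 T and NK cell markers, 0 were past it by edgeR (5 at an unadjusted p under 0.05, 4 by DESeq2, 0 adjusted over the list alone). Icos, Ctla4, Cd2 and Cd247 had log2 fold changes of 2.07, 2.63, 1.68 and 1.70. Of 19 B cell and plasma cell markers, 0 were past it by edgeR (7 at an unadjusted p under 0.05, 2 by DESeq2, 1 adjusted over the list alone). Prdm1, Mzb1 and Cr2 had log2 fold changes of 0.74, 1.59 and 1.59. Camera gave Benjamini-Hochberg adjusted p = 0.000556 for the T and NK list and 0.000467 for the B and plasma list (adjusted p = 0.514 and 0.553 with an estimated correlation). Neither was past the threshold in fry (adjusted p = 0.188 and 0.267). The B cell median lay 1.74 log2 units above the control mean in knockout replicate 2 and 1.22 above it in replicate 3, but 0.06 below it in replicate 1. Both list calls were lost without knockout replicate 2 (camera adjusted p = 0.133 and 0.246), where 3 and 1 single members were past the threshold, and that of the T and NK list also without control replicate 2 (0.0579). Of 5 mast cell and eosinophil markers 0 were past the threshold (4 at an unadjusted p under 0.05, 2 by DESeq2, 2 adjusted over the list alone), and the list's adjusted p was 0.651 (camera, Benjamini-Hochberg; adjusted p = 0.767 with an estimated correlation). This list was past it without control replicate 3 (0.0415). Mcpt1 stood at 1.83 ± 1 and 8.40 ± 4.22 CPM and Siglecf at 7.08 ± 2.57 and 2.21 ± 1.92 CPM.

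Smooth muscle transcripts were lower in the knockout. Actg2, the enteric smooth muscle actin, fell from 974.1 ± 225.9 to 201.7 ± 21.4 CPM, and Des, the muscle intermediate filament desmin, from 1411 ± 256 to 307.3 ± 52.8 CPM (SD, n = 3 each). Tpm1, a tropomyosin, fell from 979.3 ± 137 to 328.7 ± 14.1 CPM and Lmod1, an actin nucleator of smooth muscle, from 107.6 ± 15.2 to 38.2 ± 9.3 CPM. All 23 members of the list had negative fold changes, with a median log2 fold change of -1.50. Of these, 7 fell and 0 rose (20 and 0 adjusted over the list alone). The median lay below the control mean by 1, 2.14 and 1.60 log2 units in knockout replicates 1, 2 and 3. Of 34 genes of calcium entry and store handling, 2 fell and 0 rose (3 and 0 adjusted over the list alone), while 14 had positive and 20 negative fold changes, with a median of -0.06. The 2 were Pln, phospholamban, which restrains calcium uptake into the sarcoplasmic reticulum (57.0 ± 16 to 11.8 ± 1.6 CPM), and Atp2b1, a plasma membrane calcium pump (472.3 ± 19.8 to 207 ± 11.5 CPM). Casq2 and Slc8a1 had log2 fold changes of -2.86 and -0.95 and were not past the threshold. The list test (camera, Benjamini-Hochberg) gave adjusted p = 1.06e-27 for smooth muscle and 0.0103 for calcium handling (adjusted p = 0.209 for each with an estimated correlation). Smooth muscle genes past the threshold numbered 0, 0 and 2 without control replicate 1, 2 and 3, and 18, 17 and 0 without knockout replicate 1, 2 and 3. Calcium handling genes numbered 1, 0 and 0 and then 3, 7 and 0 in the same order, and the list call was lost without knockout replicate 2 (camera adjusted p = 0.0506).

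Other cells of the gut wall had higher medians in the knockout, unevenly between its libraries. All 26 genes of enteric neurons, glia and interstitial cells of Cajal, the pacemaker cells, had positive fold changes. By edgeR 0 of them were past the threshold (8 at an unadjusted p under 0.05, 5 by DESeq2, 0 adjusted over the list alone), and Vip, Tubb3, Gfap and Prph had log2 fold changes of 2.89, 1.38, 2.02 and 1.36. Of 34 matrix and fibroblast genes, 0 were past it by edgeR (9 at an unadjusted p under 0.05, 4 by DESeq2, 1 adjusted over the list alone). Lox, Pdgfrb, Dcn and Il13ra2 had log2 fold changes of 4.87, 1.63, 2.28 and 1.92. Of 19 endothelial genes, Vcam1, an adhesion molecule for leukocytes, rose (14.6 ± 2.0 to 34.5 ± 5.6 CPM) and 0 fell (4 and 0 adjusted over the list alone). Icam1, Selp and Madcam1 had log2 fold changes of 1.80, 4 and 1.35 and were not past it. As lists they had camera's Benjamini-Hochberg adjusted p = 3.09e-05, 0.00117 and 7.42e-07 for neurons, matrix and endothelium (adjusted p = 0.603, 0.684 and 0.514 with an estimated correlation). None of these lists was past the threshold in fry (adjusted p = 0.33, 0.49 and 0.224). Their medians stood 1.61, 1.41 and 1.83 log2 units above the control mean in knockout replicate 1 and 0.24, 0.48 and 0.18 below it in replicate 2. The calls for neurons and matrix were lost without knockout replicate 1 (camera adjusted p = 0.0609 and 0.466). Members past the threshold numbered 16, 20 and 14 without knockout replicate 2, and 0 without knockout replicate 3 or any 1 control replicate. Genes marking the distal colon (6 measured, 0 past the threshold of edgeR, 2 at an unadjusted p under 0.05, 1 by DESeq2, 0 adjusted over the list alone) had medians of 2.33, -0.36 and 1.72 in knockout replicates 1, 2 and 3. That list had a camera p of 0.178 after Benjamini-Hochberg adjustment, and was past the threshold without control replicate 3 (0.00926) or knockout replicate 2 (0.00141).

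Epithelial transport and detoxification genes were lower in the knockout as lists, unevenly between its libraries. Of 31 genes of xenobiotic metabolism, Abcb1a, a drug efflux pump, fell from 1010 ± 134 to 219.1 ± 80.3 CPM and 0 rose (8 lower and 1 higher adjusted over the list alone). Gsta4, Sult1a1 and Ces1g had log2 fold changes of 1.89, -1.84 and -2.10 and were not past the threshold. Of 37 absorptive colonocyte markers, 0 were past it by edgeR (14 at an unadjusted p under 0.05, 8 by DESeq2, 3 adjusted over the list alone). Slc9a3, the apical sodium-proton exchanger, stood at 376.2 ± 226 and 43.7 ± 21 CPM. Cyp2c55 stood at 2607 ± 832 and 192.1 ± 159.1 CPM and Ceacam20 at 220.8 ± 52.7 and 114 ± 24 CPM. Of 22 enteroendocrine and tuft cell genes, Sh2d7 fell (10.2 ± 1.5 to 1.44 ± 0.76 CPM) and 0 rose (2 and 0 adjusted over the list alone). Alox5, Sh2d6 and Gnat3 had log2 fold changes of -1.91, -2.11 and -3.13. Camera gave Benjamini-Hochberg adjusted p = 2.76e-08, 1.79e-06 and 0.000556 for these 3 lists (adjusted p = 0.323, 0.514 and 0.209 with an estimated correlation). By fry, adjusted p was 0.131, 0.188 and 0.0411. The colonocyte median lay below the control mean by 1.27, 0.16 and 0.62 log2 units in knockout replicates 1, 2 and 3, against -0.126 to 0.099 in the controls. In the same order the xenobiotic median was -1.86, -0.19 and -0.823, against -0.254 to 0.388, so knockout replicate 2 lay within the controls. The enteroendocrine and tuft cell median lay below every control in each knockout library. Members past the threshold numbered 0 without knockout replicate 3 or any 1 control replicate, 10, 8 and 7 without knockout replicate 2, and 4, 2 and 1 without knockout replicate 1.

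Lists of wound response, junctions and proliferation were also past the camera threshold, but unevenly between the knockout libraries. In the list of wound-associated and fetal-like epithelium (25 measured), Clu, clusterin, rose from 50.8 ± 4.3 to 103.7 ± 3.1 CPM and Ptgs2, cyclooxygenase 2, from 13.1 ± 5.3 to 71.8 ± 32.9 CPM. Cldn4, a claudin, fell from 66.8 ± 6.2 to 33.3 ± 4.1 CPM, and Marcksl1 had a log2 fold change of 1.94 (7 higher and 1 lower adjusted over the list alone). Among 29 tight junction and adhesion genes, Cldn4 fell and Cldn8, another claudin, rose from 12.5 ± 2.7 to 60.8 ± 28.8 CPM (1 in each direction adjusted over the list alone). Ocln and Dsg2 had log2 fold changes of -0.73 and -0.66. Among 32 proliferation genes, Pcna, the sliding clamp of DNA replication, fell from 46.3 ± 3.7 to 24.6 ± 1.4 CPM and 0 rose (2 and 0 adjusted over the list alone). Mcm6, Mcm2 and Ccne1 had log2 fold changes of -1.28, -0.60 and -0.51. Camera with Benjamini-Hochberg adjustment placed the first list higher (p = 0.0127) and the others lower (0.00212 and 0.0201), with adjusted p = 0.553, 0.603 and 0.684 with an estimated correlation. Fry gave adjusted p = 0.257, 0.33 and 0.49. In knockout replicates 1, 2 and 3 the wound response median was 0.92, -0.059 and 0.446 relative to the control mean, and the junction median -0.857, 0.115 and -0.286. The proliferation median was -0.437, 0.077 and -0.118, within the control libraries (-0.457 to 0.566). All 3 calls were lost without knockout replicate 1 (camera adjusted p = 0.0795, 0.289 and 0.289), the first also without control replicate 1 or 3 (0.0615 and 0.284) and the last also without control replicate 1 (0.758). Members past the threshold numbered 0 without knockout replicate 3 or any 1 control replicate, and 9, 3 and 2 without knockout replicate 2.

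Goblet and stem cell genes were not shifted as lists. Muc2, the main secreted mucin, stood at 1061, 9315 and 5477 CPM in knockout replicates 1, 2 and 3 and at 2852 ± 427 CPM in the control. Muc13 stood at 2338 ± 462 and 2616 ± 212 CPM, Prom1 at 636.2 ± 90.1 and 527.1 ± 435.9 CPM, and Lrig1 at 87.9 ± 6.4 and 89.9 ± 39.7 CPM. By edgeR 0 of 27 goblet cell and mucus genes and 0 of 17 stem cell and Wnt target genes were past the threshold (2 and 4 at an unadjusted p under 0.05, 2 in each list by DESeq2, 0 and 1 adjusted over the list alone). Camera's Benjamini-Hochberg adjusted p was 0.545 and 0.122. The goblet list was past the threshold without knockout replicate 1 (9.79e-05), and the stem cell list without knockout replicate 1 (0.0202) or control replicate 3 (0.037). Leaving out knockout replicate 2 put 1 and 3 members past it.

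Interferon-response, clock, adipose and respiratory genes were lower as lists by camera, although the interferon-response genes past the threshold were higher. Gbp4, a guanylate-binding protein gene, rose from 17.9 ± 3.1 to 51.5 ± 7.5 CPM and Tgtp1, an interferon-induced GTPase gene, from 10 ± 2.4 to 26.7 ± 1.7 CPM. Of the 41 interferon-response genes 0 fell, although 27 had negative fold changes, among them Ifit3 and Rsad2 at -0.90 and -1.28 (4 higher and 7 lower adjusted over the list alone). Of 18 circadian clock genes, Ciart, a repressor of the clock, fell from 27.1 ± 2.0 to 7.81 ± 0.96 CPM and 0 rose (3 lower and 1 higher adjusted over the list alone). Nr1d2, Dbp and Nfil3 had log2 fold changes of -0.61, -1.17 and 1.79. All 12 adipose tissue genes had negative fold changes and 0 were past the threshold of edgeR (5 at an unadjusted p under 0.05, 4 by DESeq2, 3 adjusted over the list alone). Cidec, Cfd, Car3 and Adipoq had log2 fold changes of -1.62, -4.35, -3.83 and -3.45. Of 27 nuclear genes of the respiratory chain 0 were past it by edgeR, at an unadjusted p under 0.05, by DESeq2 or adjusted over the list alone. Sdha, Cox6c, Ndufv1 and Ndufa2 had log2 fold changes of -0.50, -0.31, -0.27 and 0.23. Camera with Benjamini-Hochberg adjustment placed all 4 lists lower, at p = 0.0368, 0.000344, 0.000124 and 0.0465 for interferon, clock, adipose and respiratory genes (adjusted p = 0.711, 0.218, 0.286 and 0.737 with an estimated correlation). The interferon call was lost without knockout replicate 1 (0.56) or control replicate 1 or 2 (0.145 and 0.111). The respiratory call was lost without knockout replicate 1 or 3 (0.966 and 0.0646) or control replicate 1 or 3 (0.114 and 0.0502). In knockout replicates 1, 2 and 3 the interferon median was -0.545, -0.054 and -0.244, against -0.331 to 0.21 in the controls. The respiratory median was -0.62, 0.204 and -0.209, against -0.047 to 0.08. The clock and adipose medians lay below every control in each knockout library. Members past the threshold numbered 7, 3, 4 and 0 without knockout replicate 2, 4, 3, 0 and 0 without knockout replicate 1, and 0 without knockout replicate 3 or any 1 control replicate.

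**Figure D4:**
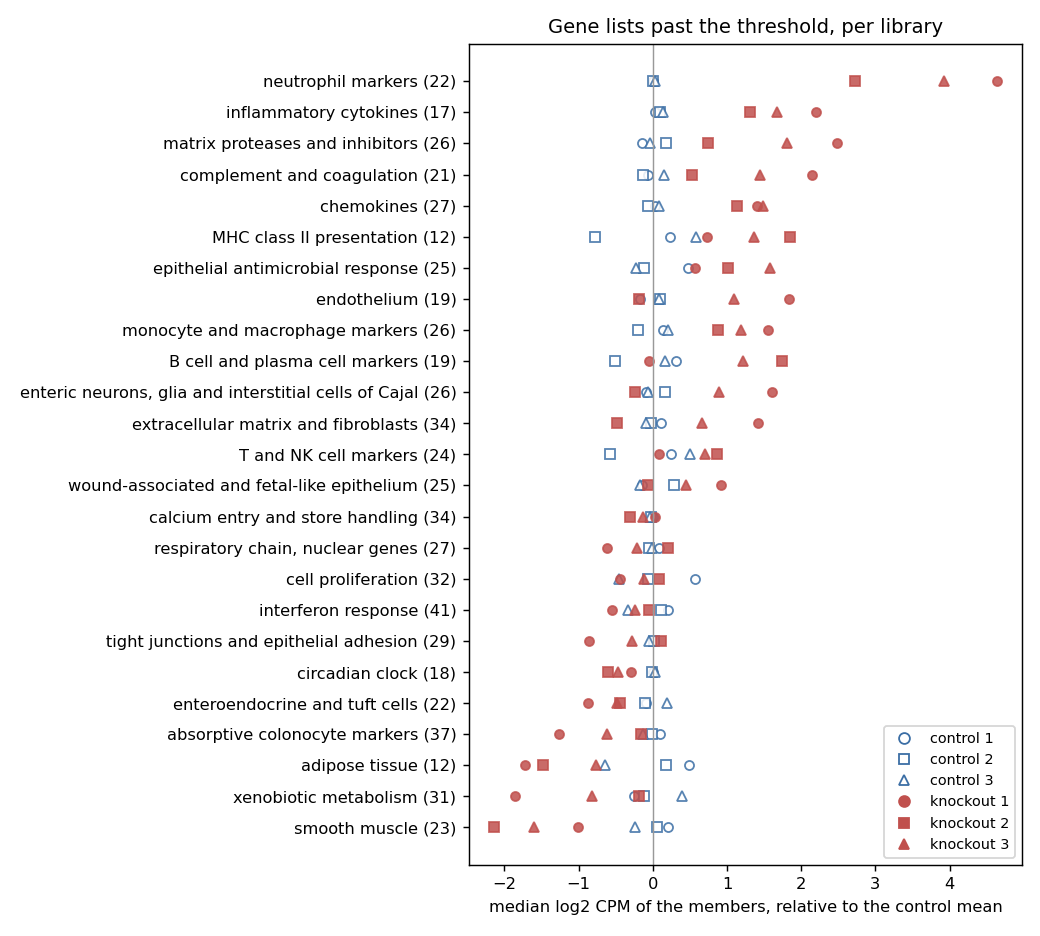
Median log2 CPM of the measured members of each gene list past the camera threshold (x axis, relative to the mean of the control libraries), 1 point per library, open for control and filled for knockout, with the number of measured members after each name. Neutrophil markers stand at 2.73 to 4.64 in the knockout libraries and smooth muscle below the controls in all of them, while matrix, neuronal and endothelial lists lie below 0 in knockout replicate 2 and above 1 in replicate 1.

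The remaining lists were not past the camera threshold, though single genes in them changed. Slc7a11, the cystine transporter, rose from 2.99 ± 0.51 to 12.0 ± 3.0 CPM among 21 oxidative stress genes (3 and 0 adjusted over the list alone). Hmox1, Gpx3 and Mt2 had log2 fold changes of 2.63, 2.95 and 3.91 and were not past the threshold. Angptl4, an inhibitor of lipoprotein lipase, rose from 4.99 ± 1.22 to 36.5 ± 21.4 CPM among 24 genes of fatty acid oxidation and ketogenesis. Ppargc1a, a coactivator of mitochondrial genes, fell there from 54.5 ± 10.5 to 24.9 ± 1.4 CPM (1 in each direction adjusted over the list alone), and Plin2 and Bdh1 had log2 fold changes of 0.38 and -0.50. Krt17, a keratin, fell from 4.82 ± 1.16 to 0.996 ± 0.120 CPM among 6 genes of squamous epithelium (1 adjusted over the list alone), and Krt15, Sbsn and Krt10 had log2 fold changes of -1.14, 1.20 and 0.24. For these 3 lists, camera's Benjamini-Hochberg adjusted p was 0.252, 0.0882 and 0.191. For oxidative stress the median was -0.13 where the mean was 0.62 and the test pointed higher, and for squamous epithelium the median was 0.10 where the mean was -0.26 and the test pointed lower. The 4 single calls were lost without knockout replicate 3 or any 1 control replicate, and that of Ppargc1a also without knockout replicate 1. Without knockout replicate 2 the lists had 8, 3 and 1 members past the threshold, and the oxidative stress list was past it (0.0275). The fatty acid list was past it without knockout replicate 2 (0.0047) or control replicate 2 (0.018).

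By edgeR, 0 members were past the threshold in the lists of other TRP channels (16 measured), calcineurin and NFAT (13), proximal colon (7), endoplasmic reticulum stress (22), glycolysis and hypoxia (24), immediate-early genes (20) and mitochondrially encoded transcripts (13). At an unadjusted p under 0.05 these lists held 6, 1, 0, 3, 6, 7 and 2 genes, and DESeq2 called 4, 0, 0, 0, 4, 5 and 2. Adjusted over the list alone there were 3 genes of glycolysis and hypoxia and 0 of the others. In list order, camera's Benjamini-Hochberg adjusted p was 0.839, 0.218, 0.701, 0.262, 0.365, 0.24 and 0.334. Endoplasmic reticulum stress was past the threshold without knockout replicate 1 (0.00487), and immediate-early genes without control replicate 2 (0.00965) or knockout replicate 2 (0.0487). Leaving out knockout replicate 2 put 2, 2, 0, 0, 5, 4 and 1 members past it. The lists of red blood cell and exocrine pancreas genes had 3 and 4 measured members, too few for a list test. The red blood cell list had enough without control replicate 2 or 3 or knockout replicate 2, and was then past the camera threshold. In them 0 were past the threshold of edgeR (3 and 1 at an unadjusted p under 0.05, by DESeq2, adjusted over the list alone, and also without knockout replicate 2). Hbb-bs stood at 1.53 ± 0.90 and 10.1 ± 6.8 CPM and Hba-a1 at 0.871 ± 0.556 and 5.62 ± 4.02 CPM, both with near-identical copies. Sycn stood at 8.02 ± 5.64 and 110.7 ± 44 CPM and Cela1 at 42.7 ± 9.1 and 38.6 ± 12.0 CPM.

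Gene ontology and pathway terms gave inflammation higher and muscle structure lower. The pathway named for Staphylococcus aureus infection (37 genes) had 5 genes higher and 0 lower. Chemokine-mediated signaling (55 genes) had 11 higher and 0 lower, and neutrophil chemotaxis (77 genes) 15 higher and 0 lower. The term test (camera, Benjamini-Hochberg) gave adjusted p = 1.39e-19, 1.6e-13 and 4.05e-13 (adjusted p = 0.398 for each with an estimated correlation). In the first, Fcgr2b and Fcgr4, receptors for the Fc part of antibodies, rose with log2 fold changes of 1.94 ± 0.24 and 2.38 ± 0.33 (SE). Masp2, a protease of the lectin pathway of complement, rose with 3.77 ± 0.51, and Cxcl2, Cxcl12, Cxcl13 and Il1b led the others. The lowest terms were I band (98 genes, 4 lower), a drug metabolism pathway (71 genes, 1 lower) and Z disc (94 genes, 4 lower). Their camera p was 0.000745, 0.000979 and 0.00164 after Benjamini-Hochberg adjustment (adjusted p = 0.981 for each with an estimated correlation). Des, Ank3, an ankyrin, and Ppp1r12a, a subunit of myosin phosphatase, led both sarcomere terms and fell with log2 fold changes of -2.20 ± 0.23, -1.27 ± 0.17 and -0.95 ± 0.14. Cyp2e1 led the pathway, where Gsta4 and Gsto1 had log2 fold changes of 1.89 and -1.03 and were not past the threshold. Of 5053 terms, 499 were past it, 468 higher and 31 lower, and 0 were with an estimated correlation (397 at an unadjusted p under 0.05). Without knockout replicate 3 there were 481 terms and without knockout replicate 2 there were 933.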

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

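The alternatives were listed before the data were examined, except 4 that were chosen after seeing the data: limma on log2(FPKM + 1) and the filter at an FPKM of 1, both part of the test planned for a table of FPKM alone, fry in either direction, and the estimated correlation for terms. Against 278 genes, the filter at an FPKM of 5 gave 119 (fewer genes tested), DESeq2 1453 and array quality weights 3588, and the cause was not tested for the latter; the other settings without a block or a left-out library gave 225 to 324. Leaving out 1 library gave 15 genes (without knockout replicate 3) to 1825 (without knockout replicate 2). The latter count kept knockout replicate 3 beside replicate 1, and these may not be independent. With the replicate number as a block there were 9 genes and 22 lists. The deviations of same-numbered libraries correlated at 0.042, -0.166 and -0.016, and those of differently numbered libraries at -0.193 to 0.194. These values showed no pairing by number, but with 3 libraries per group they cannot exclude it. Against 25 lists, an estimated correlation gave 0 and fry in 1 direction 8. These 8 were the lists of neutrophil and macrophage markers, chemokines, cytokines, antimicrobial genes, smooth muscle, calcium handling, and enteroendocrine and tuft cells. Leaving out 1 library gave 21 to 27 lists. Of these, 1 list, red blood cells, was too small to be tested with all 6 libraries (21 to 26 without it). Against 499 terms, an estimated correlation gave 0, Fisher's exact test 197, and leaving out 1 library 456 to 933. The cause of these differences was not tested. No TRPC gene was past the threshold under any setting. Of 2361 values of named genes under the alternatives, 0 reversed a called direction, 14 changes of sign concerned uncalled genes, 312 lost and 212 gained a call; of 395 values of called lists under camera with its preset correlation, 0 reversed and 36 lost the call. Trpc7, at 16 against 18 reads, was left out by the filter on low counts (adjusted p = 0.929 without the filter), and depth limits what can be seen there.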

Other observations

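Only the test of the variable segments below was written before its result was seen; all other tests of this part, the comparison with other splits included, were chosen after. A region of chromosome 17 (33 to 38 Mb) that holds histocompatibility genes, singled out after its values were seen, had 10 of 173 tested genes past the threshold (5.78%, 9 higher and 1 lower in the knockout), against 1.76% of all genes tested. The class I genes H2-Q6, H2-Q7 and H2-Q5 rose with log2 fold changes of 1.32 ± 0.22, 1.36 ± 0.20 and 1 ± 0.15 (SE), and H2-T10 and H2-M3 with 1.54 ± 0.25 and 0.97 ± 0.17. Ubd, a ubiquitin-like protein induced by cytokines, rose with 2.29 ± 0.31, while H2-Q1 fell with -2.51 ± 0.22. Of the 10 genes, 0 stayed past the threshold without knockout replicate 3 or any 1 control replicate, 6 without knockout replicate 1 and 10 without knockout replicate 2. The H2-Q genes are close copies of each other, so these values are uncertain.

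The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. The real split gave 278 genes and the highest other split 0, so 1 split gave as many. For gene lists the real split gave 25 and the highest other 23, so again 1 split gave as many. For terms the real split gave 499 and the highest other 1012, and 4 splits gave as many. Splits that mix the genotypes thus called 10 to 23 lists and 0 to 1012 terms with 0 genes past the threshold. Camera at its preset correlation therefore made many calls without a full separation of the genotypes. Each mixed split still held unequal numbers of the genotypes on its sides, so part of their difference stayed in it. The mixed splits thus cannot show how many calls arise without a genotype difference. Whether that remainder, a structure of the samples or the preset correlation gives rise to the calls was not tested.

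Knockout replicate 3 lay between knockout replicates 1 and 2, and the tables argue against a separate mouse with inflammation of intermediate degree. In such a mouse the variable segments of antibody and T cell receptor genes, whose use differs from mouse to mouse, should deviate from the weighted sum as in the controls (21.95, 25.77 and 26.84 times counting noise), but they did so by a median of 1.96 (95% bootstrap interval 1.31 to 2.67, 80 segments). This low value is not particular to replicate 3, since knockout replicate 2, fitted as 1.443 times replicate 3, gave 2.9 (1.7 to 5.84), while knockout replicate 1 gave 26.99. Material of replicates 1 and 2 combined in replicate 3 is a candidate explanation, since the deviation over all genes was 2.63 (2.54 to 2.74), where the lowest of the other libraries gave 6.91. A simulated plain sum of their reads gave 0.66, so a sum of reads alone would leave part of the deviation unexplained. Material pooled before sequencing was not simulated. The explanation by combined material was found in the same data, and would leave 2 independent knockout libraries, for which the count was 15 genes.

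Of the 278 genes, 68 differed at least 16-fold, 44 higher and 24 lower in the knockout. Not all of the 68 can lie inside chromosome segments carried along with the TRPC alleles, since 41 (60.3%) lie on 13 chromosomes without a TRPC gene. Positions cannot decide whether such a segment altered genes elsewhere, so segments as a cause are not excluded. Segments around single TRPC genes stay open: 3 of the 68 lie within 10 Mb of Trpc6 (57 genes tested), and 5 near the 6 loci other than Trpc2 together, as many as in a share of 0.43 of 10000 random placements. The 3 near Trpc6 include Mmp3 and Mmp8, neighbouring genes given above under matrix breakdown. Mmp8 stood at 17.5, 1.8 and 9.2 CPM in knockout replicates 1, 2 and 3. Of genes at least 2-fold apart between knockout replicates 1 and 2, 94.5% lay between them in replicate 3. The order of the Mmp8 values therefore cannot decide for or against a carried segment near Trpc6. Within 10 Mb of Trpc2 (160 genes tested) lie 5, as many as in a share of 0.025, but Trpc2 was singled out among 7 loci, and the fullest of 7 random placements held as many in a share of 0.16 (0.37 for all 9 of the 278 genes that lie there), with members of the Trim family next to each other among them. A difference in strain background across the genome cannot be told apart from the genotype, because the labels give no strain, and 17 of the 41 had 3 reads or fewer in every library of 1 group, 6 of them lower in the knockout; inflammation that the genotype may alter was not tested as a cause.

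Smooth muscle transcripts were lower in all 3 knockout libraries, and neither cause weighed here is settled. Less of the muscle wall in the samples would lower neurons, glia and interstitial cells of Cajal along with muscle, but the gap between the medians was at least 1.9 log2 units in each knockout library (lowest 95% bootstrap bound 1.48), against at most 0.18 in the controls. Adipose tissue, on the outer side of the wall, had medians 1.73, 1.47 and 0.77 log2 units below the control mean in knockout replicates 1, 2 and 3. Control replicate 3 stood at -0.641. The adipose gaps to smooth muscle were -0.73, 0.66 and 0.83 in the knockout libraries (95% bootstrap intervals -1.21 to 1.13, -3.74 to 2.0 and -0.99 to 1.38). These intervals are too wide to tell whether adipose tissue fell as far as muscle. Inflammation could also raise the neuronal list, so less of the muscle wall cannot be told apart from a change in muscle. Dilution by RNA of infiltrating cells stays open too: of 7 lists of resident tissue, 3 (neurons, matrix, endothelium) stayed above smooth muscle beyond the controls in every knockout library, while the 4 epithelial lists did so only in replicates 2 and 3, and in replicate 1 absorptive colonocytes fell as far as muscle (gap -0.26, 95% bootstrap interval -0.74 to 0.13). A direct effect of the missing channels on muscle was not tested.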
